A study of Mus musculus with 12 samples.

How the data were processed

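Hi-C libraries were made by the submitters from mouse cortical cultures, 6 floxed and 6 cKO. Per the labels' protocols, cells were treated with 5 µM cytosine arabinoside on day 3 in vitro against dividing glia, fixed on day 14 in 1% formaldehyde for 10 min, and processed with an Arima in situ kit to fragments of 400 bp. Per the submitters' processing notes, HiC-Pro 2.11.4 and the genome build mm10 were used. The callers of FIREs, boundaries and loops, their thresholds, and the way in which the 6 libraries of a genotype were combined are not given in the sources used here.

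The FIRE tables hold 212419 bins of 10 kb per genotype. Per the file headers, each bin has a normalized cis contact signal computed by the authors, with a mean of about 1 in each table, a deposited score that is the negative natural log of the authors' p, and the authors' mark of 0 or 1. The deposited score was checked against the signal: it equals the upper tail of a normal distribution at the signal's distance from the mean of its own table, in units of that table's SD, to within 5e-05. The p therefore ranks bins within a table and carries no replicate information, and the mark starts where this p passes under 0.05. The SD of the signal was 0.153 in floxed and 0.145 in cKO, and the lowest marked signal 1.25 and 1.24. A signal of exactly 0, which can be a missing estimate, is listed in both genotypes for 1349 bins in 194 runs and in a single genotype for 1 bin. They were kept in the main values, as the authors' p includes them, and left out of correlations and of bin-to-bin variances. Per the file headers, the boundary table gives a gap score, boundary scores of both matrices, a class and an enriched genotype per boundary on a 25 kb grid, all computed by the authors. Every positive deposited gap score is marked as enriched in cKO. The deposited loop lists hold pairs of 5 kb anchors with no strength or significance.

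Depth is unknown, since the files hold no read numbers, and no counting interval can be given. Each genotype has 1 value per bin, so no test between genotypes was run. The planned limma test needs values per library and was not used. Differences of FIRE score, cKO minus floxed, are given as values, with a difference of at least 1 counted. A FIRE was shared where the same bin was marked in both genotypes. A loop was shared where both anchors lay within 1 bin of both anchors of a loop of the other list. Boundaries were counted by the authors' own marks.

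Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10. Of 21887 protein-coding genes, 18817 overlapped at least 1 bin. The table gives no strand, so the transcription start that the plan called for is unknown, and a gene was represented by all bins of its span, the second choice of the plan. The gene's signal and FIRE score are means over those bins. In 195 genes every bin is listed at 0, among them the list members Rims1, Nrxn2, Auts2, Hnrnpu, Egr2 and Trem2. A loop belonged to a gene where an anchor overlapped the span, and a boundary was near a gene within 50 kb of the span.

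The 18 gene lists, which include markers of interneurons and of 5 non-neuronal cell types, were fixed before the data were examined, as were the comparisons, the rule for naming genes and the alternatives not said to be added. Each list's median difference in FIRE score was set against 10000 random lists of the same size, matched in 20 strata of the mean FIRE score of both genotypes, and a list outside percentiles 2.5 to 97.5 was singled out. For loops, the mean difference in loop number was set against random lists matched on loop number. These percentiles describe the tables and do not test genotype. Overlaps of bins were set against 1000 circular shifts within chromosomes.

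The text names the 10 genotype-specific FIRE bins with the largest gain and the 10 with the largest loss of FIRE score that overlap a gene, up to 3 members per list and direction with a genotype-specific FIRE, the 5 largest gap scores per genotype with the nearest gene, the 10 genotype-specific loops per genotype that touch a gene, up to 3 list members per genotype with such loops, and Satb2. The plan ordered loops by false discovery rate. As the lists give none, the shortest loops came first. The tables hold more such genes than the text names. List members near differential boundaries, named by gap score, were an addition to this rule made after the data were seen, as were Fos, Arc and Npas4, which stand for their list without values, and the loop number of Dlg2.

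On simulated data built from the real bins and 18817 genes with 200 changed, lists of 30 changed genes were recovered in 100% of draws at shifts of -0.2 and of -0.5, and lists of unchanged genes were singled out in 2.5% of draws with no shift, in 0% at -0.2 and in 5% at -0.5. The simulated noise was local and shuffled over bins, so neighbouring bins did not vary together. In the real signal difference they did (correlation of adjacent bins 0.700), so these rates do not describe lists in the real data. Simulated loops kept in place were moved by at most 1 bin, which is the tolerance itself. Their recovery in 100% of cases was therefore fixed by construction and says nothing about real loops. Loops moved farther gave 0.060% false matches. Alternatives covered the filter on low bins, scaling, thresholds, overlap tolerance, chromosomes, matching of random lists, gene window and bins listed at 0. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.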

Results

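The series measured chromatin contacts by in situ Hi-C, a proximity ligation assay that counts which pieces of the genome lie close together in the nucleus, in mouse primary cortical cultures. SATB2 is a DNA-binding protein that organizes chromatin and specifies upper-layer, callosally projecting cortical neurons. Cultures came from mice with loxP-flanked Satb2 alleles (floxed) and from mice with the same alleles and the Nes-Cre transgene, which removes Satb2 from the neural lineage (conditional knockout, cKO). There were 6 libraries per genotype, 12 in all. All cultures were collected on day 14 in vitro after 16 h of silencing with 20 µM NBQX, a blocker of AMPA and kainate receptors, and 1 h of 50 µM bicuculline, a GABA-A receptor antagonist that drives neuronal firing. The question was how the loss of SATB2 alters the 3-dimensional genome of stimulated cortical neurons. Each genotype was represented by 1 table of contact signal, 1 list of loops and a share in 1 table of boundary comparisons. The differences below therefore have no replicate check, and they describe these 2 sets of maps. Read depth per library was not given in the files used here, so the depth behind each value is unknown.

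At Satb2 itself (gene 212712, mm10 chromosome 1, 56793981 to 56981190), the mean normalized contact signal over the 20 bins of the gene was 0.911 in floxed and 0.797 in cKO cultures. The FIRE score, the negative natural log of the authors' p for a bin's local contact frequency, averaged 0.370 and 0.105 over the gene. FIREs, frequently interacting regions, are bins with unusually frequent contacts to their own neighbourhood, and none lay in Satb2 in either genotype. Each genotype had 12 loops anchored in the gene, of which 3 were found only in floxed and 2 only in cKO cultures. Bins of 10 kb do not resolve the deleted exons, so these values do not check the deletion.

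Most genes had a slightly higher local contact signal in cKO cultures: of 18817 genes with bins, 11035 were higher and 7557 lower. The largest negative difference in FIRE score in a genotype-specific FIRE over a gene was in Dlg2, which encodes the postsynaptic scaffold PSD-93: 88 of its bins were FIREs in floxed and 11 in cKO cultures, and the mean signal over the gene was 1.23 and 1.09. The bin at chromosome 7, 91390001 to 91400000, inside Dlg2, had a signal of 1.47 in floxed and 1.22 in cKO cultures, with FIRE scores of 6.77 and 2.75. Ppfia2, which encodes the active-zone protein liprin-alpha-2, had 25 and 14 FIRE bins. Marchf1, a membrane-bound ubiquitin ligase gene, had 12 and 0, and Fam135b had 17 and 9.

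Across the genome, 6669 of 212419 bins (3.14%) were FIREs in floxed and 5428 (2.56%) in cKO cultures. They shared 4215 bins, which left 2454 FIREs in floxed cultures alone and 1213 in cKO cultures alone. The excess of floxed-only FIREs lay in bins more than in genes, since 794 genes held a FIRE of floxed cultures alone and 762 held a FIRE of cKO cultures alone. The share of bins called FIRE per autosome averaged 3.20% ± 0.871 (SD over 19 autosomes) in floxed and 2.62% ± 0.821 in cKO cultures, and cKO had fewer FIREs on 18 of 21 chromosomes. Without the sex chromosomes the genotype-specific FIREs numbered 2435 and 1203. The FIRE score was lower in cKO by at least 1 in 2955 bins and higher by at least 1 in 837, so 22.1% of the bins that differed by this much were higher. After quantile normalization of the genotypes these numbers were 2170 and 1328, with 38.0% higher. Signals correlated across bins (Pearson's r = 0.936, Spearman's rho = 0.922, over bins and not over replicates).

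Many of these calls lay near the threshold, since the bins called only in floxed had a median p of 0.0782 in cKO cultures and the reverse set a median p of 0.0685 in floxed cultures. Demanding a p above 0.1 in the other genotype left 734 floxed and 187 cKO bins, and leaving out the 1349 bins listed at 0 in both tables, which widen each table's spread, gave 3026 and 2131, out of 10097 FIREs in floxed and 9202 in cKO cultures.

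**Figure D1:**
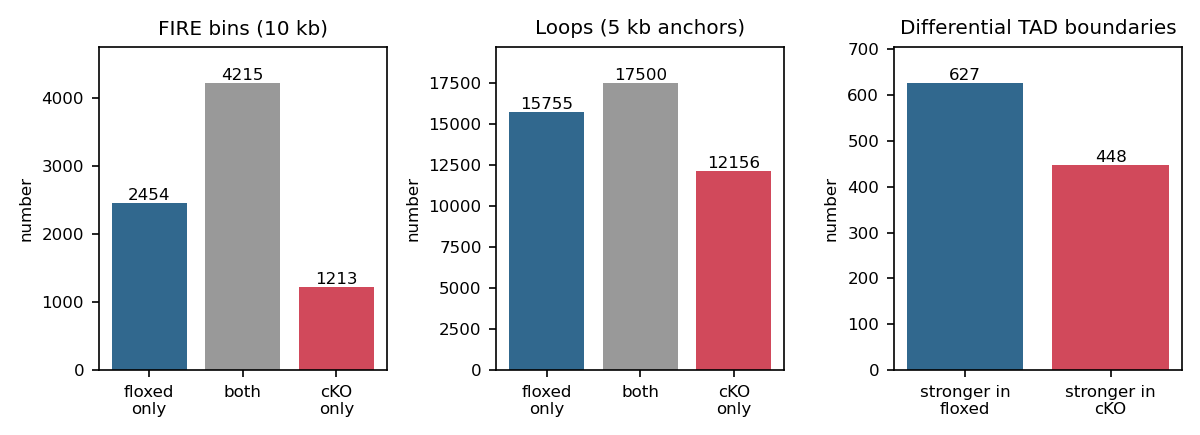
Bars show numbers of FIRE bins, loops and differential TAD boundaries, with floxed cultures in blue, cKO cultures in red and features of both in grey; each vertical axis is a count that starts at 0. Floxed cultures have more genotype-specific features in each panel, with 2454 against 1213 FIRE bins, 15755 against 12156 loops and 627 against 448 boundaries.

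Genes of glutamatergic synapses carried lower local contact signal in cKO cultures. Of 40 measured glutamate receptor and postsynaptic scaffold genes, 25 had a lower and 15 a higher mean signal, and 9 held FIREs found only in floxed cultures. Besides Dlg2, Grin2b, which encodes an NMDA receptor subunit, had a mean signal of 1.11 in floxed and 0.999 in cKO cultures and 2 FIRE bins in floxed cultures alone. Grm5, encoding a metabotropic glutamate receptor, had 1.13 and 1.08 and 6 such bins. The reverse, a FIRE bin in cKO cultures alone, was found in Camk2a, which encodes a synaptic plasticity kinase, and in Homer2, where the signal of the bin was nearly equal at 1.25 in floxed and 1.24 in cKO cultures. The list's median difference in FIRE score, cKO minus floxed, was -0.153, below all 10000 random lists of genes matched on FIRE score. With the bins of the gene ends alone it was -0.0402 (percentile 0.22), so its size depends on the gene body.

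Presynaptic and vesicle genes followed the same order: 18 of 28 had a lower and 8 a higher signal, while Rims1 and Nrxn2 were listed at 0 in both genotypes. Nrxn1, which encodes a presynaptic adhesion receptor, had 1.13 in floxed and 1.01 in cKO cultures and 10 FIRE bins in floxed cultures alone. Rims2, an active-zone scaffold gene, had 1.36 and 1.27 with 7 such bins, and Nrxn3 1.09 and 1.04 with 1. Unc13b, a vesicle priming gene, held 1 FIRE bin found only in cKO cultures. The list's median difference was -0.110, at percentile 0.030 of the random lists, and -0.0518 at the gene ends alone (percentile 0.49). Rims1 and Nrxn2 entered the median of -0.110 with a difference of 0. Without bins listed at 0, a setting added after the data were seen, the median was -0.15 (percentile 0.0).

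Inhibitory receptors and ion channels were also lower. Among GABA receptor genes 10 of 13 had a lower signal, with a median difference in FIRE score of -0.177 (percentile 0.040) and of -0.0982 at the gene ends alone (percentile 0.35). Gabrb1 had a mean signal of 1.16 in floxed and 1.07 in cKO cultures, Gabrb3 1.18 and 1.13, and Gabbr2 1.06 and 1.02. Among voltage-gated ion channel genes 27 of 38 were lower, with a median difference of -0.0663 (percentile 0.22) and of -0.0287 at the gene ends alone (percentile 0.82). Kcnh7, a potassium channel gene, had 19 FIRE bins in floxed cultures alone, Cacna2d1, a calcium channel subunit gene, had 13, and Hcn1, which encodes a channel of the hyperpolarization-activated current, had 12. Cacna1d held 5 and Scn1a 2 FIRE bins found only in cKO cultures. The position of the channel list was lost when random lists were matched on the floxed FIRE score alone (percentile 2.67) or on gene length as well (percentile 13.9).

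Of 50 genes in which mutations cause inherited intellectual disability or autism, Satb2 among them, 36 had a lower signal in cKO cultures and 13 a higher one, and Auts2 was listed at 0 in both. Chd2, a chromatin remodeller gene, had 1.25 in floxed and 1.16 in cKO cultures and 5 FIRE bins in floxed cultures alone. Tsc2, which encodes a brake on mTOR signalling, had 1.25 and 1.31 and 3 FIRE bins in cKO cultures alone. The median difference in FIRE score was -0.108, below all random lists. The list shares Satb2, Grin2b, Nrxn1 and other genes with the lists above, and 8 of its members are sex-linked; over autosomal members alone the median difference was -0.0620 (percentile 0.050). The X chromosome as a whole had a mean signal of 0.916 in floxed and 0.863 in cKO cultures.

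The 4 Hox clusters, which hold homeobox genes of body patterning that the cortex largely keeps silent, had higher local contact signal in cKO cultures. Of 38 listed Hox genes 37 were higher, and the median difference in FIRE score was 0.133, above all random lists. Mean signal over the genes of each cluster was 0.895 in floxed and 0.925 in cKO cultures for Hoxa, 0.931 and 0.985 for Hoxb, 1.16 and 1.21 for Hoxc, and 0.726 and 0.772 for Hoxd. Hoxc13 held 1 FIRE bin found only in cKO cultures, with a signal of 1.21 and 1.29. Members of a cluster are neighbours and not independent. With at most 1 gene per Mb, the median difference was 0.364, at percentile 99.2. That setting leaves only 1 gene per cluster, the first in the list, so its median rests on 4 genes and its size depends on which were kept.

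Layer identity and activity genes stood inside the range of random lists. Upper-layer and callosal projection neuron genes had a median FIRE score difference of -0.0122 (percentile 3.32, 11 of 20 lower), and deep-layer and subcerebral projection neuron genes 0.0357 (percentile 57.1, 6 of 21 lower). Cux2, an upper-layer transcription factor gene, held 1 FIRE bin found only in cKO cultures. Activity-regulated genes, which include Fos, Arc and Npas4, had a median difference of -0.0025 (percentile 4.47, 21 of 39 lower). The activity list passed below percentile 2.5 in 4 of the alternatives tried after the data were seen, and the upper-layer list in 1.

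Markers of interneurons and of non-neuronal cells in such cultures also stood inside this range. The median difference in FIRE score was 0.0204 for interneuron genes (percentile 52.7), 0.0256 for astrocyte genes (percentile 49.1), 0.0361 for oligodendrocyte lineage genes (percentile 71.4), 0.0246 for microglia genes (percentile 44.4), 0.0656 for endothelial and mural cell genes (percentile 62.7) and 0.0106 for radial glia and progenitor genes (percentile 58.9). Axon guidance and cell adhesion genes had 0.0132 (percentile 12.5), with 2 FIRE bins in floxed cultures alone at Epha5, and 3 in floxed and 1 in cKO cultures alone at Nrcam. Genome architecture and chromatin genes had 0.0025 (percentile 19.6): 5 members held FIREs of floxed cultures alone and 5 held FIREs of cKO cultures alone. The cohesin genes Nipbl and Stag1 held 4 and 3 FIRE bins found only in floxed cultures, the cohesin release factor gene Wapl and the insulator gene Ctcf 2 and 1 found only in cKO cultures, and the remodeller gene Smarca4 1 of each kind. Housekeeping genes had 0.0258 (percentile 36.6). Across all 18817 genes with bins the median difference was 0.0361. In all, 5 of 18 lists stood below and 1 above the random lists. By chance 0.9 would lie outside if members varied like randomly placed genes, which neighbours such as the Hox genes do not. Lists also share members, so their positions are not independent.

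**Figure D2:**
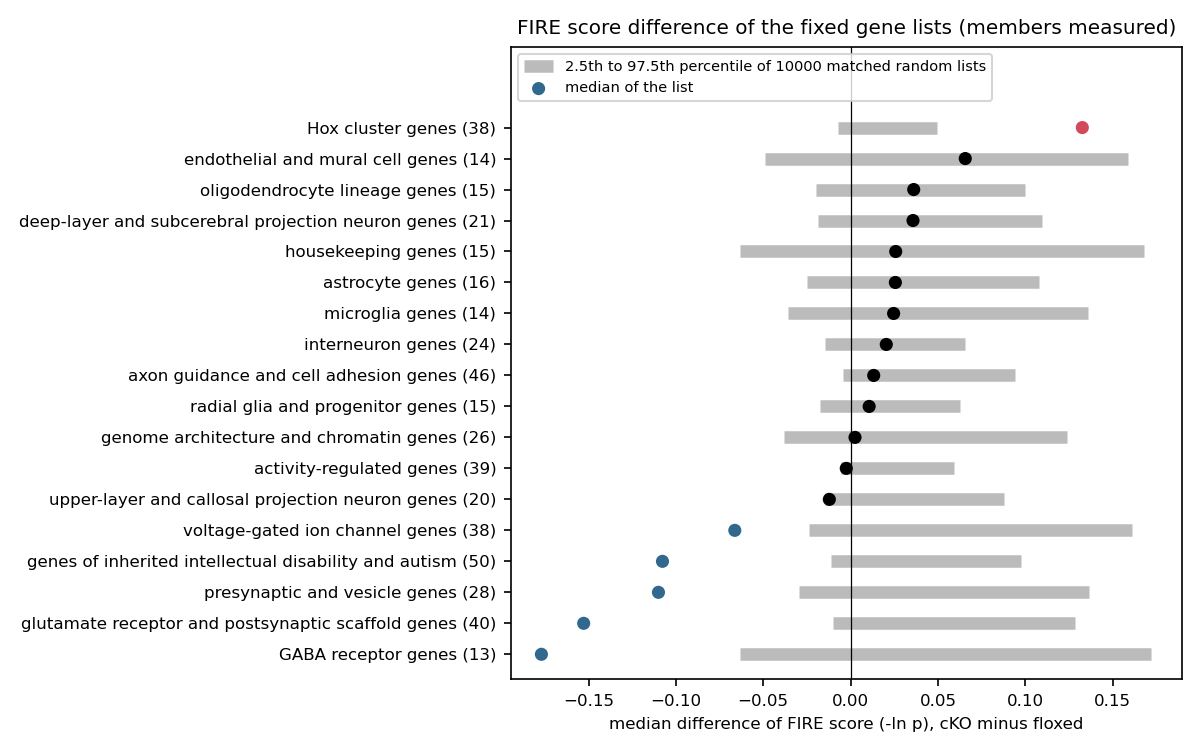
Each point is the median difference in FIRE score (negative natural log of p, cKO minus floxed) over the measured members of a gene list, and each grey bar spans percentiles 2.5 to 97.5 of 10000 matched random lists. The 5 lists in blue lie below their bars, the Hox list in red lies above its bar at 0.133, and the 12 lists in black lie inside.

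The largest positive differences in FIRE score in genotype-specific FIREs over genes exceeded the largest negative ones, with 9.90 at the Y-linked gene Kdm5d and 7.17 at Ifi47 against -4.01 at Dlg2. Among autosomal bins only the first rank kept this order. The next gains were 3.78 at Slfn4 and 2.15 at Vps35, and the next losses -3.79 at Ppfia2 and -3.55 at Dlg2. On autosomes, a bin at Ifi47, an interferon-induced GTPase gene (chromosome 11, 49090001 to 49100000), had a signal of 1.20 in floxed and 1.55 in cKO cultures, and a bin at Slfn4, a Schlafen family gene (chromosome 11, 83170001 to 83180000), had 0.929 and 1.31. Vps35, which encodes a retromer subunit, held 3 FIRE bins found only in cKO cultures, and the corepressor gene Ncor1 held 6. Cnot6l, a deadenylase gene, held 3, and Phf14 held 4 beside 1 found only in floxed cultures. Sex-linked genes stood on both sides: a bin at Kdm5d on the Y chromosome had 1.25 and 1.66, a bin at Usp9y had 1.22 and 1.62, and a bin at Usp9x on the X chromosome had 1.39 and 1.08. Over the 49 Y bins the mean signal was 1.48 in floxed and 1.62 in cKO cultures, and 85.7% of X bins were lower in cKO cultures.

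**Figure D3:**
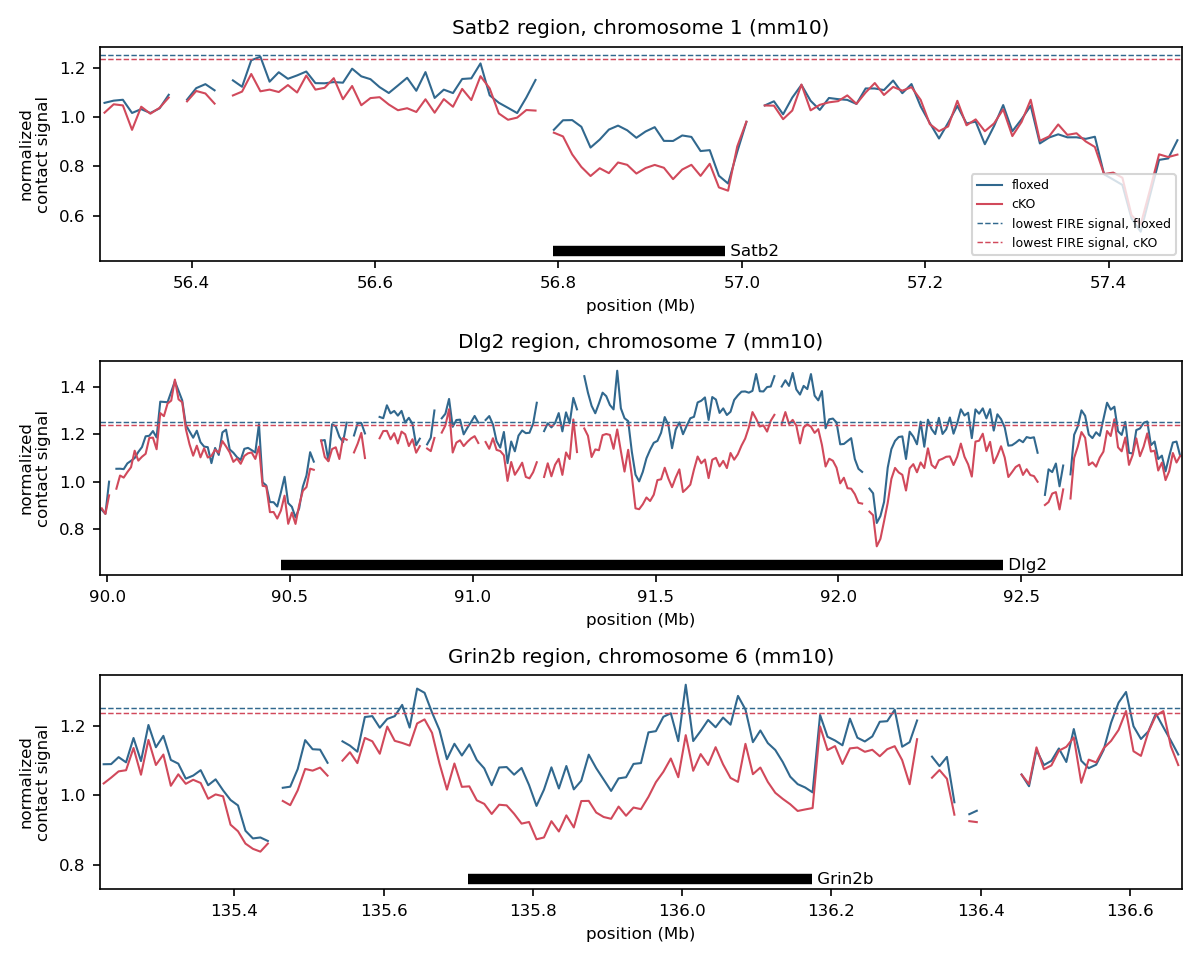
Lines trace the normalized contact signal per 10 kb bin in floxed (blue) and cKO (red) cultures against mm10 position in Mb around Satb2, Dlg2 and Grin2b; black bars are the genes, gaps are bins the tables do not hold, and dashed lines mark the lowest signal called FIRE, 1.25 in floxed and 1.24 in cKO. Over Dlg2 the floxed line passes its dashed line in 88 bins and the cKO line in 11, and over Satb2 the lines average 0.911 and 0.797.

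Boundaries between topologically associating domains (TADs) were stronger in floxed cultures more often than in cKO cultures. In the authors' deposited table, 1075 of 9500 boundaries (11.3%) were differential, 627 enriched in floxed and 448 in cKO cultures. Floxed cultures had more of them on 19 chromosomes in the authors' deposited table, and cKO cultures on 1. The floxed excess lay in changes of strength alone. These made up 328 of the floxed-enriched and 144 of the cKO-enriched boundaries in the authors' deposited table. Merges, of which 223 were listed, were all enriched in floxed, and splits, of which 209 were listed, were all enriched in cKO cultures, while 75 and 94 were complex in the authors' deposited table. The names merge and split thus followed the sign of the gap score without exception, and they are no separate result on direction. A further 130 boundaries in the authors' deposited table were shifted.

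The largest gap scores, the standardized differences in which positive values are enriched in cKO cultures, marked few known neuronal genes. In the authors' deposited table the cKO-enriched boundaries included 1 inside Cttnbp2, which encodes a cortactin-binding protein of dendritic spines (chromosome 6, 18375000, gap score 13.7), 1 near the homeobox gene Barx2 (chromosome 9, 31925000, 15.3), 1 near Slfn1 (chromosome 11, 83100000, 11.8) and 1 near Gm16434 (chromosome 14, 7225000, 16.4). The floxed-enriched boundaries in the authors' deposited table included 1 near Ece1, an endothelin-converting enzyme gene (chromosome 4, 137975000, -11.5), 1 near the defensin gene Defa24 (chromosome 8, 21750000, -12.7) and 1 at Gm40365 (chromosome 6, 47675000, -11.9). The highest 2 floxed-enriched gap scores of the authors' deposited table, on X at 35150000 (-15.7) and on chromosome 14 at 52900000 (-15.6), had no protein-coding gene within 50 kb, nor had the cKO-enriched boundary on chromosome 4 at 122500000 (15.8).

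Some layer genes lay near differential boundaries. Of 20 upper-layer genes, 6 had a floxed-enriched boundary of the authors' deposited table within 50 kb and 0 a cKO-enriched one. These included Satb2 (gap score -3.20 in the authors' deposited table), Bhlhe22 (-3.70), a transcription factor gene of callosal neurons, and Lmo4 (-3.58). Of 21 deep-layer genes, 1 had a floxed-enriched boundary of the authors' deposited table nearby, Sox5 (-2.79), and 4 a cKO-enriched one, among them Nfib (5.54), Tle4 (4.41) and the netrin receptor gene Unc5c (2.75). The difference between these counts was not tested.

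Synaptic genes and markers of several non-neuronal cell types lay more often near floxed-enriched boundaries, which were also the more frequent kind in the genome. Of 40 glutamate receptor and scaffold genes, 8 lay near floxed-enriched and 2 near cKO-enriched boundaries of the authors' deposited table, with gap scores of -5.61 at the synaptic adhesion gene Nlgn1, -4.36 at the AMPA receptor gene Gria2 and 4.13 at Grm7. Among presynaptic genes the numbers in the authors' deposited table were 3 and 1, with -5.42 at Nrxn1, and among GABA receptor genes 2 and 0, with -5.48 at Gabrg2. Ion channel genes had 4 and 6 in the authors' deposited table, including both -8.33 and 2.38 at Kcnh5 and 3.84 at the sodium channel gene Scn2a. Of the 6, Scn2b and Scn4b lay beside a single boundary. Axon guidance genes had 10 and 8 in the authors' deposited table, with -6.74 at Cdh10 and 4.79 at Ncam2, and Cntnap2 counted on both sides. Astrocyte and microglia genes each had 3 and 0 in the authors' deposited table, with all 3 microglia genes (C1qa, C1qb and C1qc) beside a single boundary. Oligodendrocyte lineage and progenitor genes each had 2 and 0 and interneuron genes 0 and 2 in the authors' deposited table. No Hox, endothelial or housekeeping gene had a differential boundary of the authors' deposited table within 50 kb. These counts were set against no background.

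Loops were fewer in cKO cultures, most of all the long ones. The lists held 33255 loops in floxed and 29656 in cKO cultures, a ratio of 0.892, and the ratio was 0.927 for loops up to 100 kb and 0.787 for loops of 1000 to 2000 kb. With both anchors within 1 bin of 5 kb, 17500 loops were shared, 52.6% of the floxed and 59.0% of the cKO list, against 0.286% of the floxed list after the cKO list was moved by 500 kb. This left 15755 loops in floxed and 12156 in cKO cultures alone, with more floxed-only loops on all 20 chromosomes that had loops. The median span of genotype-specific loops was 315 kb in floxed and 270 kb in cKO cultures. With identical bins required, 26320 and 22721 loops were specific to a genotype. The lists give no strength or significance per loop, and a list's length depends on read depth, which is unknown here.

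Synaptic and ion channel genes were anchors of fewer loops in cKO cultures, in numbers inside the range of random lists matched on loop number. Glutamate receptor and scaffold genes had 253 loops in floxed and 209 in cKO cultures (percentile 4.52), presynaptic genes 142 and 113 (percentile 3.22) and ion channel genes 235 and 193 (percentile 8.06). Loops anchored in Dlgap1, a postsynaptic scaffold gene, numbered 33 in floxed and 19 in cKO cultures, those in Grm7 13 and 6, and those in Dlg1 10 and 5. Loops found only in cKO cultures lay at Shank1, a scaffold gene with 4 and 5 loops, the kainate receptor gene Grik2 with 4 and 4, and Nlgn1 with 6 and 5. The neurexin gene Nrxn3 had 26 and 13, Nrxn1 28 and 23, the synapsin gene Syn3 13 and 13, and the potassium channel genes Kcnd2 14 and 7 and Kcnq3 14 and 13. Dlg2, the list member with most FIREs in floxed cultures alone, had 30 and 35.

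Other lists had loops in both directions. Upper-layer genes had 114 loops in floxed and 104 in cKO cultures and deep-layer genes 119 and 122, with Cux1 at 9 and 9, Cdh13 at 20 and 21, Nfia at 19 and 15 and Nfib at 10 in each. Activity-regulated genes had 109 and 101. Of these, Trib1 had 2 and 6, the immediate-early gene Egr3 2 and 4, and the synaptic pentraxin gene Nptx2 3 and 1. Axon guidance genes had 373 and 322, among them the adhesion gene Nrcam with 12 and 7 and the repellent gene Slit1 with 7 and 4. The interneuron list, at 74 and 62, held Erbb4, a neuregulin receptor gene, with 7 and 2. The GABA receptor list had 81 and 69, the intellectual disability and autism list 265 and 241, the Hox list 68 and 68, and the housekeeping list 23 and 15. None of the 18 lists stood outside percentiles 2.5 to 97.5 of its random lists for loop number.

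The shortest genotype-specific loops that touched a gene spanned 25 to 30 kb and mostly joined parts of the same gene. In floxed cultures alone they included loops within Nptn, which encodes the synaptic adhesion protein neuroplastin (chromosome 9, 58590001 to 58595000 with 58620001 to 58625000), Usp37, R3hdm1, Tnpo3, Agbl3, Tbc1d15, Marchf6 and Zfp654, and loops joining Pmpcb to Dnajc2 and Gsta1 to Gm3776. In cKO cultures alone they included loops within Gmps, a gene of guanine nucleotide synthesis (chromosome 3, 63985001 to 63990000 with 64010001 to 64015000), Ralgds, Naa15, Usp53, Tmem135 and Trappc11. Loops in cKO cultures alone also lay within Fxr1, with Dnajc19 at an anchor, and within Kcnu1, with Ash2l at an anchor. Another joined Txnl4b to Dhodh, and 1 had an anchor in Hfm1.

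Genotype-specific loop anchors and differential boundaries met more often than chance placement gives, in every pairing of genotypes. Anchors of floxed-only loops coincided with boundaries enriched in floxed in the authors' deposited table in 402 bins, 2.4 times the mean of 1000 circular shifts, and with cKO-enriched boundaries in 186 bins (1.61 times). Anchors of cKO-only loops coincided with floxed-enriched boundaries of the authors' deposited table in 288 bins (2.1 times) and with cKO-enriched ones in 205 (2.17 times). All 4 numbers exceeded those of every shift. Anchors of shared loops and non-differential boundaries were not counted in this way. The numbers therefore do not separate changed features from a general meeting of loop anchors and boundaries. FIREs found only in cKO cultures coincided with anchors of floxed-only loops in 171 bins, 1.31 times the shifted mean and above all shifts, and with anchors of cKO-only loops in 119 bins (1.12 times, percentile 89.1). FIREs found only in floxed cultures coincided with anchors of floxed-only loops in 294 bins (1.11 times, percentile 95.3) and with anchors of cKO-only loops in 198 (0.926 times, percentile 13.8); with a stricter FIRE threshold the last ratio was 1.31 (percentile 99.0). FIREs of a single genotype met differential boundaries of the authors' deposited table in only 2 to 10 bins per pairing. With floxed-enriched boundaries of the authors' deposited table the ratios were 0.540 for floxed-only FIREs (percentile 4.4) and 0.430 for cKO-only FIREs (percentile 4.25), and with cKO-enriched ones 0.393 (percentile 2.45) and 0.310 (percentile 4.25). A stricter threshold turned the ratios for floxed-enriched boundaries of the authors' deposited table to 1.97 and 1.30, inside the range of the shifts. For cKO-enriched boundaries of the authors' deposited table the ratios stayed below 1 in each setting, with 0.278 and 0.271 within 1 bin. At the stricter threshold there was no shared bin, which was inside the range of the shifts (percentiles 17.95 for floxed-only and 32.0 for cKO-only FIREs).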

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

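All tests in this part were chosen after the results were seen. The sex chromosomes stood out because their signal belongs to no planned comparison: over 49 Y bins the mean normalized contact signal was 1.62 in cKO against 1.48 in floxed cultures, while X bins had a median difference of -0.0504. A scaling difference between the tables is argued against, since the median X difference was -0.0597 after quantile normalization, and so is a loss over genes alone, since X bins outside protein-coding genes had a median difference of -0.0394. A larger share of male cells in the pooled cKO cultures would lower X and raise Y throughout; 100% of 17 windows of 10 Mb on X were lower and 89.8% of Y bins higher in cKO cultures, but these values restate the pattern and leave the explanation open. The labels used here give no sex for the pups. An effect of SATB2 on the sex chromosomes themselves was not tested.

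The lists of glutamate receptor, presynaptic, GABA receptor, ion channel and intellectual disability genes had lower FIRE scores in cKO cultures than matched random lists. Gene length was matched too in 8 classes, and 4 of the 5 lists stayed below their random lists, the exception being the ion channel list. This argues against length between classes as the whole cause. Length within the longest class was not controlled: the share of autosomal genes lower in cKO was 50.8% at 100 to 200 kb and 63.7% at 200 to 500 kb. A part played by length in lists of long genes stays open. The narrower spread of the cKO signal is argued against as the whole cause, because 5 of 5 stayed below after quantile normalization. A lower share of neurons could give this pattern and would raise the lists of non-neuronal cell types. Of those 5 lists, 3 had medians above their random lists and none stood outside percentiles 2.5 to 97.5. Lists of neuron types were mixed, with upper-layer genes at percentile 3.32, deep-layer genes at 57.1 and interneuron genes at 52.7. The tables therefore cannot decide. Loss of SATB2 and the Nes-Cre transgene itself, which only the cKO cultures carry, both separate the groups by design. They also stay open, and they cannot be told apart from each other or from cell composition here.

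Fewer FIREs and fewer loops were called in cKO cultures. A mark set by each table's own mean and spread moved the FIRE gap in both directions. With mean and spread taken without the bins listed at 0 there were 10097 FIREs in floxed and 9202 in cKO cultures, 1.10 times as many in floxed. With a single signal cut the gap was wider: 4280 cKO bins reached the lowest marked floxed signal, against 6669 floxed bins. At the lowest marked cKO signal there were 8148 floxed bins, against 5428 cKO bins. A single cut assumes that both genotypes share a signal scale, yet the cKO signal has the narrower spread. Its SD without bins listed at 0 was 0.121, against 0.131 in floxed cultures. These counts therefore cannot decide whether the cut set in each table makes the gap, and the cause of the gap stays open. A lower sequencing depth of the cKO map would add counting noise. The bin-to-bin variance of the signal was 0.978 times that of floxed cultures (95% interval over 19 autosomes 0.969 to 0.987), but as a share of all variance it was 1.15 times as large. This variance also holds real local structure, and the interval describes the chromosomes of 1 pair of maps. Lower depth as a cause of the fewer FIREs therefore stays open. For loops, lower depth could shorten the list and remove long loops first: the ratio of cKO to floxed loops was 0.849 times as high in the longest as in the shortest class, which an altered structure would give too. For loops, depth and genotype cannot be told apart, because the files hold no read numbers.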

How the results depend on the processing

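The alternatives of autosomes only for FIREs, FIRE scores and lists, matching on gene length, contact signal in place of score, quantile normalization of lists, gene ends, 1 gene per Mb, thinning of the loop list and bins listed at 0 were chosen after seeing the data. Of the list settings, 119 kept their side of the percentile limits and of the random median. No paired analysis was possible because the files hold 1 value per genotype and no value per library; the replicate block, the other value tested, the pseudocount and leave-one-out were not run for that reason, and the stricter and equal-length loop lists by false discovery rate were not run because the loop lists give none. Transcription start bins were not run for want of strand.

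Bins with higher FIRE score in cKO numbered 1328 after quantile normalization, 7509 at a difference of 0.5, 67 at 2 and 2257 without bins listed at 0; lower bins numbered 12942, 280 and 4531 in the last 3 settings. FIREs in floxed alone numbered 656 at p under 0.01, 1601 with neighbours within 1 bin counted as shared and 734 with the other p above 0.1, and in cKO alone 273, 753 and 187. FIREs in cKO alone numbered 2131 without bins listed at 0, when the totals were 10097 in floxed and 9202 in cKO. They numbered 2788 with the top 5% of bins in each genotype, where both genotypes have equal numbers by construction. Differential boundaries numbered 248 and 188 (floxed, cKO) at a gap score of at least 3 and 328 and 144 for strength changes alone, and specific loops 26320 and 22721 with identical bins. With the floxed loop list thinned to the cKO length, 14048 loops were specific to each genotype, again equal by construction.

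Overlap ratios that came to stand outside the shifts were 1.19 for floxed FIREs with floxed-only anchors and 1.25 for cKO FIREs with cKO-only anchors within 1 bin, 1.46 for cKO FIREs with cKO-only anchors at the stricter threshold and 0.271 for cKO FIREs with cKO boundaries within 1 bin. At the stricter threshold 3 ratios reversed: 1.31 for floxed FIREs with cKO-only anchors, now outside the shifts, and 1.97 and 1.30 for floxed and cKO FIREs with floxed boundaries, inside them on few bins. Floxed FIREs with cKO boundaries had a ratio of 0 at the stricter threshold, on few bins, and no longer stood outside. The upper-layer list (-0.0122, autosomes) and the activity list (-0.0025 on autosomes and with length matching, -0.0024 for signal, -0.0059 after quantile normalization) passed below the random lists. The ion channel list (-0.0663) no longer did so when matched on floxed score alone or on length. Lists inside the limits crossed the random median in 18 settings and stayed inside: deep-layer at 0.0357 (floxed matching, autosomes), interneuron at 0.0204 (floxed matching), 0.0246 (autosomes) and 0.0163 (1 gene per Mb), astrocyte at 0.0344 (quantile) and 0.0336 (gene ends), microglia at 0.0440 (without bins at 0) and 0.0552 (1 gene per Mb), progenitor at 0.0106 (without bins at 0, floxed matching, autosomes, length) and 0 (quantile), axon guidance at 0.0132 (length), architecture at 0.0422 (autosomes) and 0.0773 (quantile), and housekeeping at 0.0782 (autosomes). The cause was not tested for these lists and overlaps. Unknown depth limits every count of FIREs, differential boundaries and loops.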

Other observations

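The genes of this part were chosen after their values were seen, and no test was run on them. Local contact signal differed with gene length on the autosomes. Of 8988 genes up to 20 kb, 32.7% had a lower signal in cKO cultures (median difference 0.0138), against 63.7% of 719 genes of 200 to 500 kb (-0.0109) and 61.6% of 216 longer genes (-0.0132). Autosomal bins outside protein-coding genes had a median difference of 0.0103 and those inside -0.0009. Among genes over 500 kb the largest negative difference was at Celf2, a neuronal RNA-binding protein gene, with 1.03 in floxed and 0.879 in cKO cultures and no FIRE in either. Csmd1 had 1.09 and 0.972, the Rho exchange factor gene Kalrn 1.17 and 1.06, the synaptotagmin gene Syt1 1.02 and 0.907, and the reelin adaptor gene Dab1 1.09 and 0.992. Other long genes had higher signal in cKO cultures: Sox6, a transcription factor gene of interneurons, had 0.975 and 1.03, Cadps2 0.972 and 1.03, Erbb4 0.916 and 0.964, and Foxp2, a deep-layer transcription factor gene, 0.951 and 0.993.

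Genes picked for their loop numbers differed in both directions. Csmd1 had 20 loops in floxed and 5 in cKO cultures, the potassium channel gene Kcnb2 17 and 5, the synaptic adhesion gene Lrrc4c 28 and 16, and Ntm, which encodes neurotrimin, 34 and 23. In the other direction, Bcl11b, which encodes the subcerebral identity factor CTIP2, had 5 loops in floxed and 11 in cKO cultures, with a signal of 0.720 and 0.774. Tbc1d5 had 15 and 23, Cdkal1 14 and 22, Sgcz 6 and 13, and Btbd9 12 and 19.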
